A study of Mus musculus with 28 samples.

How the data were processed

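Per the labels' protocols, rods marked by an Nrl-driven fluorescent protein were dissociated with papain and purified by flow cytometry, and libraries were made with a stranded mRNA kit and read as 125-base pairs on a HiSeq 2500. Per the submitters' processing notes, reads were quantified with kallisto 0.42.4 and edgeR 3.32.1 on GRCm38.p5. Reads were not mapped again here.

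The deposited gene table held the authors' estimated gene counts (expected counts, fractional), which the tests used after rounding. In genes with a single transcript, with at least 50 counts, the ratio of gene count to transcript count lay between 0.959 and 1.1 (5th to 95th percentile), so the gene counts had been rescaled. The deposited CPM table equalled each gene count divided by the library total, on the CPM scale, with a largest difference of 5.8e-11, and carried no further scaling. The transcript table, which holds the authors' expected counts per transcript, served only for Pde6b and for the check on near-identical libraries. In each of the 3 tables, 1 column without a sample in the labels was not used here.

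The design was fixed before the data were examined for 28 libraries. Afterwards, 2 libraries, P6 rd1 replicates 1 and 3, proved near-identical and were averaged, a departure from that design, so 27 samples were tested, 12 rd1 and 15 WT. The result with all 28 kept apart is given with the other alternatives.

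Genes were kept with edgeR's filterByExpr on the 10 groups of age and genotype (18608 of 45594 genes), and libraries were scaled by TMM. In R 4.3.3, edgeR 4.0.16 fitted a quasi-likelihood model with 1 mean per group and 17 residual degrees of freedom. Contrasts were rd1 over WT at each age, their average with equal weight, the 4 degrees of freedom interaction of genotype and age, the P10 effect minus the P2 effect, and P10 over P2 in WT. The effect at P8 minus the mean of the other ages was added after the data were seen. P-values were adjusted by Benjamini-Hochberg over the genes tested in each contrast, with a threshold of 0.05. The edgeR tests are two-sided. Log2 fold changes are edgeR estimates. Their SE was calculated back from the test, as the absolute log2 fold change divided by the square root of its F statistic. It is thus approximate, above all where 1 group is near 0 counts. CPM means have SD over samples. A gene whose libraries in a group were all at 0 was compared with a floor of 3 counts per library. That floor covers counting error only, since reads without molecular identifiers are not independent molecules. The interval of the odds ratio near Pde6b is that of Fisher's exact test over genes.

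For naming, the rule set beforehand took Pde6b, the 8 genes with the largest change in each direction among those past the threshold, with a mean log2 CPM of at least 1 and no overlap between the libraries compared (for the average, the same sign at all 5 ages). It also took up to 4 members of each list by p. Pseudogenes and predicted genes by symbol were only counted, and for the interaction the 8 genes with the smallest p were taken. Of these, the text gives those that show each group. Named copies, clusters and genes near Pde6b fall outside that rule and were chosen after their values were seen.

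Before the data were examined, 31 gene lists were fixed, for photoreceptor functions, markers of other retinal cells, metabolism and stress, of which 30 were tested. Each list was tested in each contrast with limma 3.58.1 camera on the fitted counts, at the preset correlation of 0.01 and again with an estimated correlation. Adjustment was over the 180 tests of the 6 genotype contrasts. The lists were also tested with fry, which tests whether the list's genes move on balance in 1 direction. The WT and P8 contrasts were adjusted over their own lists. The count adjusted over the list alone repeats the adjustment within its members.

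DESeq2 1.42.0 and limma-voom with library weights were the other tools. To check the method, counts were simulated with 200 changed genes in each contrast. At single ages, 23% to 42% of 2-fold and 65% to 74% of 4-fold changes were recovered, and on the average 73% and 96%. All calls of changed genes had the right direction, and false calls made up 0% to 9.91%, the highest at P10. Replicate numbers did not pair the samples, since the 9 pairs of an rd1 and a WT library with the same age and number had residuals that correlated at -0.238 to 0.138 with a median of 0.0328.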

Results

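The series held 28 RNA-seq libraries of mouse rod photoreceptors, sorted by flow cytometry through the green fluorescent protein of an Nrl promoter transgene. The rods came from wild-type mice (WT) and from mice homozygous for rd1, a loss-of-function allele of Pde6b. Pde6b encodes the beta subunit of the rod cGMP phosphodiesterase, the enzyme that light switches on, and rods without it degenerate after birth. The 5 ages sampled were postnatal days 2, 4, 6, 8 and 10 (P2 to P10). There were 2 rd1 and 2 WT libraries at P2, 2 and 3 at P4, 3 and 4 at P6, 4 and 2 at P8, and 2 and 4 at P10. In all, 13 libraries were rd1 and 15 were WT.

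The rod genes Nrl and Nr2e3, which encode transcription factors of rod identity, were abundant in every group. Mean Nrl ranged from 1790 CPM (counts scaled to the library total) at P4 in WT to 3090 CPM at P10 in rd1, and mean Nr2e3 from 2070 CPM at P2 in rd1 to 3060 CPM at P8 in rd1. Nnt, a mitochondrial transhydrogenase gene that some laboratory strains carry in a defective form, was read in both genotypes. It stood at 28.7 CPM in WT and 30.4 CPM in rd1 at P2. At P10 it stood at 13.7 ± 1.95 CPM (SD, n = 4) in WT and 8.09 ± 0.0566 CPM (n = 2) in rd1. These levels do not establish the strain of either line. Total counts per library ran from 11.1 to 21.4 M (mega).

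Depth split the libraries by genotype at 4 of the 5 ages, and 1 abundant transcript did at P2, P4 and P10. The 9 rd1 libraries of P2, P4, P6 and P10 held 16 to 21.4 M counts, and the other 19 libraries held 11.1 to 15 M. Gm42418, a predicted transcript, lay between 93.8 and 283.7 CPM in those 9 libraries. It lay between 1.56 and 45.99 CPM in 18 of the 19 others and reached 318.2 CPM in P6 WT replicate 1. Fos, an immediate early gene that cell dissociation can raise, spanned 144.4 to 833.7 CPM in the 9 and 4.803 to 591.1 CPM in the 19. Only P8 had both genotypes in the same depth class, so at P2, P4, P6 and P10 genotype and depth class cannot be told apart.

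**Figure D1:**
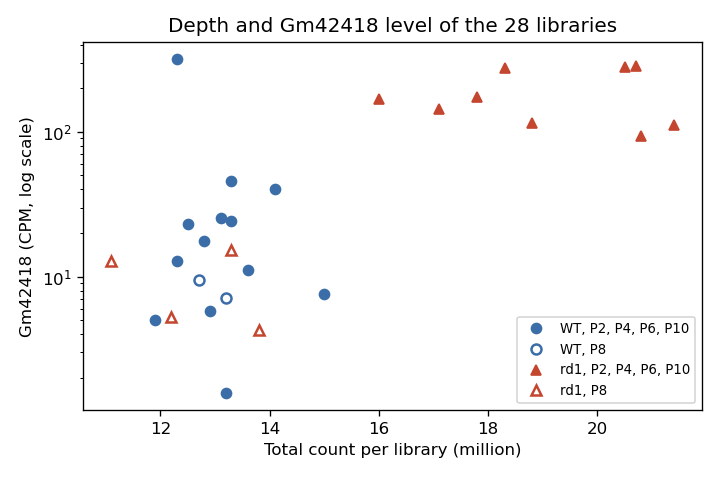
Each point is 1 of the 28 libraries, with its total count in M on the x axis and its Gm42418 level in CPM on a log y axis, for WT (circles) and rd1 (triangles), open symbols for P8. The 9 rd1 libraries of P2, P4, P6 and P10 sit at 16 M counts or more, and the 4 rd1 libraries of P8 sit among the WT libraries.

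P6 rd1 replicates 1 and 3 were near-identical. Their counts differed with a chi-square per degree of freedom of 1.33, against 8.67 to 115 for the other 28 pairs of libraries within a group. They entered every test as 1 averaged sample, and 27 samples were compared. Both Xist and Ddx3y, transcripts of the inactive X and of the Y chromosome, exceeded 10 CPM in 19 libraries, while 4 libraries had Xist alone and 5 had Ddx3y alone. At P10, WT replicates 2, 3 and 4 had Xist at 3.8, 0.821 and 2.825 CPM. It stood at 1027 and 1154 CPM in rd1 at P10 and at 2418 and 2497 CPM in WT at P2. At P8 both WT libraries had Ddx3y at 0.1664 and 0.3951 CPM. Sex was therefore not balanced in these comparisons, and its part in them was not tested. The 19 libraries with both transcripts probably held cells of males and females, and so of more than 1 animal. The labels do not say how animals were divided among replicates, so the p-values measure spread between these samples. P6 WT replicate 1 stood apart in genes detected (27119) and in the share of counts in its top 10 genes (11.5%), and P10 WT replicate 5 stood apart in Fos (591.1 CPM).

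Pde6b itself, the gene with the rd1 allele (ENSMUSG00000029491, chromosome 5, 108388391 to 108432397 on GRCm38), was lower in rd1 rods at every age. It stood at 114 ± 23.9 CPM (SD, n = 2) in rd1 and 586 ± 178 CPM (n = 2) in WT at P2, and at 1390 ± 240 CPM (n = 2) and 3240 ± 1020 CPM (n = 4) at P10. The log2 fold changes of rd1 over WT were -2.37, -1.77, -1.67, -1.99 and -1.26 from P2 to P10. Averaged over the ages, the log2 fold change was -1.81 ± 0.15 (SE, adjusted p = 4.79e-09). In the transcript table the full-length coding transcript Pde6b-001 averaged 316 CPM in rd1 and 1310 CPM in WT. The retained-intron transcripts Pde6b-002 and Pde6b-003 averaged 209 and 30.7 CPM in rd1 and 327 and 46.8 CPM in WT. Left out 1 at a time, 5 libraries ended the Pde6b call while the log2 fold change stayed negative. At P4 it was -1.61 without P4 rd1 replicate 2 (adjusted p = 0.11). At P6 it was -1.57 without P6 rd1 replicate 2 (0.109), and the call was also lost without replicate 1. At P10 it was -1.07 without P10 rd1 replicate 1 (0.136), and the call was also lost without replicate 2.

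**Figure D2:**
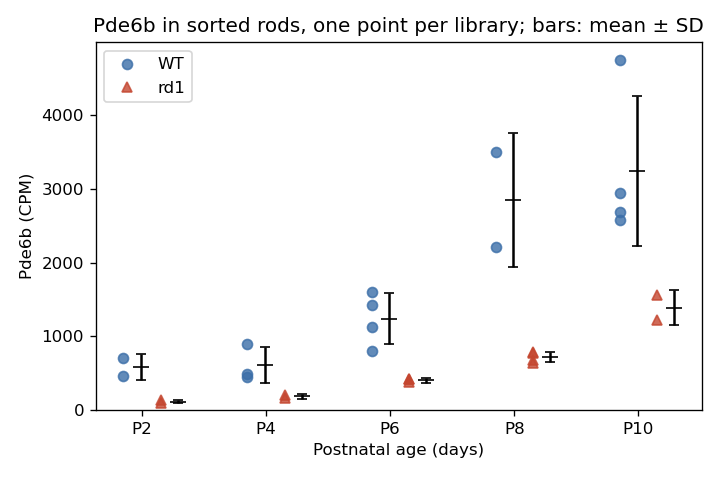
Pde6b level in CPM (y axis) by postnatal age (x axis), 1 point per library, WT as circles and rd1 as triangles; black bars give the mean and SD with the near-identical P6 rd1 pair averaged. At each age every rd1 library lies under every WT library, from 114 against 586 CPM at P2 to 1390 against 3240 CPM at P10.

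At P2, the comparison asked how rd1 rods differed soon after birth, before rod loss. Several genes were close to absent in rd1. Slc15a2, a peptide transporter gene, fell with a log2 fold change of -8.16 ± 0.70, Col17a1, a collagen of epithelial anchoring, with -6.70 ± 0.48. Myof, a membrane repair gene, stood at -4.56 ± 0.43. Duxbl1, a double homeobox gene (chromosome 14, 25978577 to 25990088), had 0 counts in both rd1 libraries and 13.2 CPM in WT. It was at least 83.1-fold lower against a floor of 3 counts per library. Phf24 (-5.23), Cldn34c1 (-3.81), Hfm1 (-3.47) and the mitochondrial serine tRNA gene mt-Ts1 (-4.91) were lower too. Sfrp4, which encodes a secreted Wnt modulator, rose by 4.39 ± 0.59, Orm2, an acute-phase protein gene, by 3.92, and Nipal1 by 3.50. Klhl33 rose by 3.33, Acot1, an acyl-CoA thioesterase gene, by 3.16, Bspry by 3.13 and CAAA01147332.1 by 4.08.

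Among the gene lists at P2, the immediate early and dissociation genes had a median log2 fold change of 1.96. Of 18 tested members 2 were higher, Junb (3.42) and Jund (2.34), 0 lower and 16 not past the threshold (6 higher adjusted over the list alone; camera adjusted p = 1.06e-05, adjusted p = 0.984 with an estimated correlation). The progenitor and proliferation genes had a median of 0.87 with 0 of 30 members past the threshold (5 higher adjusted over the list alone; adjusted p = 1.7e-05, and adjusted p = 0.984 with an estimated correlation). Hes5 stood at 2.38 and Mcm2 at 1.04 there, neither past the threshold. The cholesterol synthesis list had a median of 0.29 with 0 of 20 members past it, alone or over all genes (adjusted p = 0.0314, and adjusted p = 0.984 with an estimated correlation). Single members of other lists also changed. Phb, a prohibitin, fell by 0.71 and Pfkp, a phosphofructokinase, by 1.49. The cystine transporter gene Slc7a11 rose by 1.16, the cone genes Thrb by 1.23 and Cnga3 by 1.62, the neurofilament gene Nefh by 0.99 and the lactate transporter gene Slc16a8 by 1.53.

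In total 522 of 18608 genes passed the adjusted p of 0.05 at P2, 265 higher and 257 lower, and 207 of them were pseudogenes or predicted genes. The count was 239 without P2 rd1 replicate 1, 207 without P2 rd1 replicate 2, 219 without P2 WT replicate 1, 900 without P2 WT replicate 2 and 784 without P6 WT replicate 1. Leaving out 1 library ended the call of 12 of the 25 genes named as past the threshold at P2. These were CAAA01147332.1, Junb, Acot1, mt-Ts1, Jund, Thrb, Cnga3, Slc7a11, Pfkp, Nefh, Phb and Slc16a8. The highest adjusted p was 0.399 (Junb without P2 WT replicate 1). The progenitor list did not pass without P2 WT replicate 2 (median 0.48, adjusted p = 0.0563), nor the cholesterol synthesis list without P2 rd1 replicate 2 (0.18, adjusted p = 0.316) or P2 WT replicate 2 (adjusted p = 0.0727).

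At P4, 2 of 23 phototransduction genes were higher in rd1 than in WT rods. Cnga1, the rod cGMP-gated channel subunit, rose by a log2 fold change of 2.17 ± 0.39 and Rcvrn, the calcium sensor recoverin, by 2.07 ± 0.50. The guanylate cyclase genes Gucy2f (1.37) and Gucy2e (0.95) did not pass the threshold. The genes with the largest changes were Scand1 (4.96), Nrtn (4.60), a neurotrophic factor gene, Masp2 (4.03), a complement protease gene, CAAA01147332.1 (3.60), Erdr1 (3.50), Pcsk1n (3.46), Bspry (3.39) and Sox30 (3.34) upward. Downward they were Duxbl1 (-6.42 ± 0.64), Col17a1 (-6.04 ± 0.45), mt-Ts1 (-5.64), Tmsb15b1 (-4.89), Eps8l1 (-4.68), Slc15a2 (-4.65), Hfm1 (-3.81) and Ahcy (-3.08), the gene of the enzyme that breaks down S-adenosylhomocysteine. Fos stood at 442 ± 48.1 CPM (n = 2) in rd1 and 122 ± 180 CPM (n = 3) in WT at this age.

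The phototransduction list had a median log2 fold change of 0.61 at P4, with 2 of 23 members higher and 21 not past the threshold (4 higher adjusted over the list alone; adjusted p = 6.14e-05, adjusted p = 0.984 with an estimated correlation). The dissociation and immediate early list had a median of 1.24 with 1 of 18 members higher, Jund at 2.31 (5 adjusted over the list alone; adjusted p = 6.27e-05). The unfolded protein and integrated stress response list had a median of 0.46 with 0 of 23 members past the threshold (6 higher adjusted over the list alone; adjusted p = 0.00119), Atf5 at 0.88 and Trib3 at 1.41 among them. Glycolysis and lactate genes had a median of 0.30 with 1 of 29 higher, the hexokinase gene Hk1 at 1.08 (1 adjusted over the list alone; adjusted p = 0.0128). The proteins encoded in the mitochondrial genome had a median of -0.49 with 1 of 13 lower, mt-Nd3 at -2.64 (2 lower adjusted over the list alone; adjusted p = 0.00371). Markers of microglia and macrophages had a median of 1.29 (0 of 16 past, alone or over all genes; adjusted p = 0.00355) and markers of amacrine and horizontal cells a median of -0.65 (0 of 15, alone or over all genes; adjusted p = 0.0283). Each of these lists had an adjusted p = 0.984 with an estimated correlation. Single genes of other lists were Slc7a11 (1.45), the matrix gene Impg1 (1.41), the photoreceptor transcription factor Rax (1.55), the mitochondrial genes Chchd10 (1.63) and Phb2 (0.47), Thrb (1.04) and Nefh (1.24), all higher.

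Of all genes tested, 549 passed at P4, 299 higher and 250 lower, 222 of them pseudogenes or predicted genes. The count fell to 243 without P4 rd1 replicate 1, 195 without P4 rd1 replicate 2, 310 without P4 WT replicate 1 and 302 without P4 WT replicate 3, and was 873 without P6 WT replicate 1. The call ended without some single library for Scand1, Nrtn, CAAA01147332.1, Erdr1, Pcsk1n, Rcvrn, Impg1, Rax, Hk1, Chchd10, Phb2, Jund, mt-Nd3, Thrb and Nefh. Their adjusted p reached 0.494 (Impg1 without P4 rd1 replicate 1). Without P4 rd1 replicate 1 the phototransduction list had a median of 0.35 and did not pass (adjusted p = 0.12), nor did the glycolysis list (adjusted p = 0.0542). The microglia list did not pass without P4 WT replicate 2 (adjusted p = 0.0569), nor the amacrine and horizontal list without P4 rd1 replicate 2 (0.0567) or P4 WT replicate 2 (0.069). The dissociation median spanned 0.79 without P4 WT replicate 1 to 1.93 without P4 WT replicate 2, past the threshold in both.

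At P6, 170 higher and 131 lower genes had also passed at P4, where 4.37 and 2.92 were expected by chance. Sox30 rose by 3.72 ± 0.32, Masp2 by 3.41, Capn11 by 3.34, Klhl33 by 3.33, Sfrp4 by 3.06, Nipal1 by 2.70, Fam69a by 2.43 and Orm2 by 2.41. Lower genes were Col17a1 (-5.61 ± 0.44), the pseudogene AA623943 (-4.79), mt-Ts1 (-4.32), Phf24 (-4.21), Tmem92 (-4.15), Eps8l1 (-3.97) and Slc15a2 (-3.64). Duxbl1 again had 0 counts in the rd1 samples, against 25.4 CPM in WT, at least 143-fold lower. The spindle checkpoint gene Bub1b fell by 1.89 and mt-Nd3 by 1.96, while Slc7a11 rose by 1.08 and Nefh by 0.98.

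The nuclear subunits of oxidative phosphorylation had a median log2 fold change of 0.25 at P6. Of 72 members 0 were higher and 1 was lower, against the sign of the median, and the others were not past the threshold (1 lower adjusted over the list alone; adjusted p = 4.96e-05). The stress response list had a median of 0.34 (0 of 23 past, alone or over all genes; adjusted p = 0.00119), the dissociation list 0.95 (0 of 18, alone or over all genes; adjusted p = 0.000745) and phototransduction 0.32 (0 of 23, 1 higher adjusted over the list alone; adjusted p = 0.0223). The medians were -1.19 for amacrine and horizontal cell markers (0 of 15 past, 5 lower adjusted over the list alone; adjusted p = 0.000371) and -1.09 for vessel markers (0 of 12, 1 lower adjusted over the list alone; adjusted p = 0.0137). Müller glia markers, with a median of 0.21, and bipolar markers, with 0.06, did not pass. Gad1, an enzyme of inhibitory neurons, was at -2.07 and the vessel receptor Tek at -3.72, neither past the threshold. The mitochondrially encoded list had a median of -0.47 with 1 of 13 lower, mt-Nd3 (2 adjusted over the list alone; adjusted p = 0.0206). Each of the lists named here as past the threshold had an adjusted p = 0.984 with an estimated correlation.

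The total at P6 was 489 genes, 272 higher and 217 lower, 188 of them pseudogenes or predicted genes. By DESeq2 the balance turned, with 365 higher and 439 lower. The edgeR total depended on single libraries. It was 196 without P6 rd1 replicate 1, here the averaged pair, 213 without P6 rd1 replicate 2, and 1023 without P6 WT replicate 1, the library with the most genes detected. Single left-out libraries ended the call of Capn11, Orm2, mt-Ts1, Phf24, Tmem92, Bub1b, Slc7a11, mt-Nd3 and Nefh, with adjusted p of up to 0.358 (mt-Nd3 without P6 rd1 replicate 1). The mitochondrially encoded list had a median of -0.01 without P6 WT replicate 1 (adjusted p = 0.717) and -0.185 without P6 rd1 replicate 1 (adjusted p = 0.579), so its lower median rested on those libraries. Without P6 rd1 replicate 2 it was -0.92 (adjusted p = 0.000262). The dissociation median was 1.72 without P6 WT replicate 1 (adjusted p = 1.27e-09) and 0.58 without P6 WT replicate 4 (adjusted p = 0.00718). Without P6 WT replicate 3 the phototransduction list (adjusted p = 0.285) and the vessel list (0.0849) did not pass, nor did they without P6 rd1 replicate 1 (0.187 and 0.0868). The amacrine and horizontal median was -0.70 without P6 WT replicate 3 (adjusted p = 0.00371).

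At P8, the 1 age at which both genotypes were of the same depth, 3 of 23 phototransduction genes and 8 of 29 glycolysis and lactate genes were lower in rd1. Among phototransduction genes Guca1b, a guanylate cyclase activator, fell by 2.77 ± 0.52, Gnat1, rod transducin, by 2.00 ± 0.49 and Kcnv2, a photoreceptor potassium channel subunit, by 1.38. The glycolytic genes Gpi1 (-0.59), Pgam1 (-0.64), Pgk1 (-0.63) and Ldha (-0.66) fell as well. Duxbl1 (-8.87 ± 0.57), AA623943 (-5.86), Col17a1 (-5.68), Tmem92 (-5.55), Eps8l1 (-4.91), Bub1b (-3.99), Slc15a2 (-3.85) and Ahcy (-3.66) were lowest, and Sfrp4 (5.45 ± 0.65), Klhl33 (4.21), Masp2 (3.92), Tuba1c (3.34) and Orm2 (3.25) were higher. The Y-linked genes Eif2s3y (9.30), Ddx3y (7.48) and Kdm5d (4.07) were also higher, in an age where both WT libraries had Ddx3y under 10 CPM.

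The phototransduction list had a median log2 fold change of -0.63 at P8, with 3 of 23 members lower and 20 not past the threshold (5 lower adjusted over the list alone; adjusted p = 1.45e-05, adjusted p = 0.984 with an estimated correlation). The glycolysis and lactate list had a median of -0.45 with 8 of 29 lower and 21 not past it (12 lower adjusted over the list alone; adjusted p = 2.74e-06, adjusted p = 0.984 with an estimated correlation). Cholesterol synthesis genes had a median of -0.34 with 0 of 20 past (4 lower adjusted over the list alone; adjusted p = 0.00724), Mvd at -0.92 and Fdft1 at -0.82 among them. Markers of Müller glia had a median of 0.61 with 0 of 13 past, alone or over all genes (adjusted p = 0.0137). Both had an adjusted p = 0.984 with an estimated correlation. Other genes were the actin bundler Fscn2 (-1.12), Pcna (-1.12), which has a pseudogene copy, Mfn2 (-0.54), Acat1 (-0.55), Pdia4 (-0.77) and Ier3 (-1.14), all lower, and Slc7a11 (1.82), Gngt2 (1.51), Sdhc (0.61) and Nr4a1 (1.32), all higher. The dissociation list had a median of -0.12 (adjusted p = 0.846). The lists of outer segment genes (adjusted p = 0.132), photoreceptor transcription factors (0.652) and the ribbon synapse (0.207) did not pass.

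In all, 688 genes passed at P8, 219 higher and 469 lower, 199 of them pseudogenes or predicted genes. Without P8 WT replicate 1 the count was 171, the median of the phototransduction list was -0.09 (adjusted p = 0.532) and that of the glycolysis list -0.41 (adjusted p = 2.44e-06). Without P8 WT replicate 2 the phototransduction median was -1.15 (adjusted p = 4.82e-13). The Müller glia list did not pass without P8 WT replicate 1 (adjusted p = 0.077) or P8 rd1 replicate 1 (0.0553). The count was 419 without P8 rd1 replicate 2 and 382 without P8 rd1 replicate 4. Without P8 WT replicate 1 the calls of Guca1b, Gnat1, Kcnv2, Gpi1, Pgam1, Pgk1, Ldha, Fscn2, Gngt2, Pcna, Mfn2, Acat1, Pdia4, Ier3, Nr4a1, Sdhc, Tuba1c and the 3 Y-linked genes ended. The highest adjusted p there was 0.97 (Gnat1). Guca1b then stood at -0.95 and Gnat1 at -0.35, while Gpi1 (-0.62), Pgam1 (-0.72), Pgk1 (-0.56), Ldha (-0.60), Mfn2 (-0.60) and Nr4a1 (1.37) stood close to their values with all libraries.

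At P10, near the onset of rod loss in this model, 11 of 18 dissociation and immediate early genes and 10 of 23 stress response genes were higher in rd1. The heat shock genes Hspa1b and Hspa1a rose by 6.16 ± 0.46 and 5.90 ± 0.51, Nr4a1, an immediate early nuclear receptor gene, by 4.07 and the chaperone gene Hsph1 by 1.77. Eif2ak3, the PERK kinase that senses unfolded protein, rose from 53.11 ± 8.87 CPM (SD, n = 4) in WT to 204.7 ± 43.6 CPM (n = 2). Chac1 rose by 3.98, Atf5 by 1.66 and Asns by 1.62, targets of the integrated stress response. The granule gene Ptprn rose by 4.96 ± 0.32, Scand1 by 6.14, Nrtn by 5.41, Erdr1 by 4.63, Sox30 by 4.53 and Csrnp1 by 4.50. Duxbl1 (-7.23), mt-Ts1 (-5.73), Eps8l1 (-4.70), Col17a1 (-4.69), Tnr (-3.37), Ahcy (-3.26), Slc15a2 (-3.20) and the noncoding RNA Platr15 (-3.19) fell.

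By list, the dissociation and immediate early genes had a median log2 fold change of 2.26 at P10, with 11 of 18 higher and 7 not past the threshold (12 adjusted over the list alone; adjusted p = 2.95e-16, adjusted p = 0.68 with an estimated correlation). Fos stood at 685 ± 210 CPM (n = 2) in rd1 and 178 ± 276 CPM (n = 4) in WT. The stress response list had a median of 0.67 with 10 of 23 higher and 13 not past it (15 adjusted over the list alone; adjusted p = 7.07e-10, adjusted p = 0.68 with an estimated correlation). Nuclear subunits of oxidative phosphorylation had a median of 0.36 with 20 of 72 higher, 1 lower and 51 not past (28 and 1 adjusted over the list alone; adjusted p = 8.69e-06, adjusted p = 0.984 with an estimated correlation). Cox6a1 stood at 1.83, Cox8a at 1.24 and Atp5d at 1.21. The mitochondrially encoded list moved the other way, with a median of -0.72 and 2 of 13 lower, mt-Nd3 at -1.99 and mt-Co2 at -1.27 (2 adjusted over the list alone; adjusted p = 0.015, adjusted p = 0.984 with an estimated correlation). Antioxidant genes had a median of 0.31 with 7 of 24 higher, Srxn1 at 1.03 and Slc7a11 at 0.99 among them (9 adjusted over the list alone; adjusted p = 0.00724, adjusted p = 0.984 with an estimated correlation).

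Markers of other cell types moved in both directions at P10. Microglia and macrophage markers had a median log2 fold change of 1.93 with 6 of 16 higher, Aif1 at 3.04 and the complement gene C1qc at 2.68 (10 adjusted over the list alone; adjusted p = 4.96e-05). Müller glia markers had a median of 0.71 with 3 of 13 higher, Clu at 1.22 and Apoe at 1.39 (5 adjusted over the list alone; adjusted p = 0.000745). Ganglion cell markers had a median of 0.62 with 2 of 13 higher, Nefh at 1.45 and Isl2 at 1.32 (2 adjusted over the list alone; adjusted p = 0.0399). Cone markers had a median of -0.96 with 3 of 14 lower, the cone phosphodiesterase gene Pde6c (-3.14), Kcne2 (-3.08) and the opsin gene Opn1mw (-2.46), and 1 higher, Gngt2 at 2.08 (9 lower and 1 higher adjusted over the list alone; adjusted p = 0.00453). Vessel markers had a median of -1.98 with 5 of 12 lower, Tek (-3.86), Rgs5 (-3.26) and Pecam1 (-1.84) among them (9 adjusted over the list alone; adjusted p = 0.00731). Bipolar markers had a median of -1.15 with 2 of 15 lower, Grik1 (-2.41) and Scgn (-1.99) (7 adjusted over the list alone; adjusted p = 0.00936). Each of these cell type lists had an adjusted p = 0.984 with an estimated correlation.

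The phototransduction list did not pass at P10. Genes of other lists past the threshold were the phosphodiesterase gene Pde10a (3.05), the kinase gene Camk2g (2.46-fold), the death genes Bbc3 (2.28) and Bax (0.55), Cebpd (3.14) and Mt1 (2.14) of the damage response, Srebf2 (1.03), the glucose transporter gene Slc2a1 (0.62), Pkm (0.54), Aldoa (0.71), and the citric acid cycle gene Mdh2 (0.58), all higher. The calcium release channel genes Ryr3 (-1.54) and Ryr2 (-0.81), Pfkfb2 (-1.68), Rpgrip1 (-1.42) and Rpgr (-0.99) were lower.

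The total at P10 was 2352 genes, 1454 higher and 898 lower, 456 of them pseudogenes or predicted genes. Sex was not balanced between the genotypes at this age. The count was 463 without P10 rd1 replicate 2, 1062 without P10 rd1 replicate 1 and 1434 without P10 WT replicate 3. Of the 61 genes named here as past the threshold, 31 kept the call without any 1 library, among them Hspa1b, Hspa1a, Ptprn, Eif2ak3, Chac1, Atf5, Asns, Nr4a1, Cox6a1, Clu, Pde6c, Kcne2 and Pde10a. The other 30 lost it without some library, among them Pde6b, Cox8a, Atp5d, Aif1, C1qc, Apoe, Opn1mw, Tek, Pecam1, Rgs5, Scgn, Grik1, Bbc3, Bax, Mt1, Slc2a1, Pkm, Aldoa, Mdh2, mt-Nd3, mt-Co2, Srxn1 and Slc7a11. Their adjusted p reached 0.472 (Aldoa without P10 rd1 replicate 2). Of the 11 lists past the threshold 3 did not pass without some library. These were the ganglion cell list (adjusted p up to 0.239, without P10 WT replicate 5), the bipolar list (up to 0.141, without P10 rd1 replicate 2) and the mitochondrially encoded list (up to 0.0688, without P10 WT replicate 2). The Müller glia median was 0.44 without P10 WT replicate 5 (adjusted p = 0.0251) and 1.15 without P10 WT replicate 2. The median of the nuclear oxidative phosphorylation list was 0.23 without P10 rd1 replicate 2 (adjusted p = 0.00851).

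**Figure D3:**
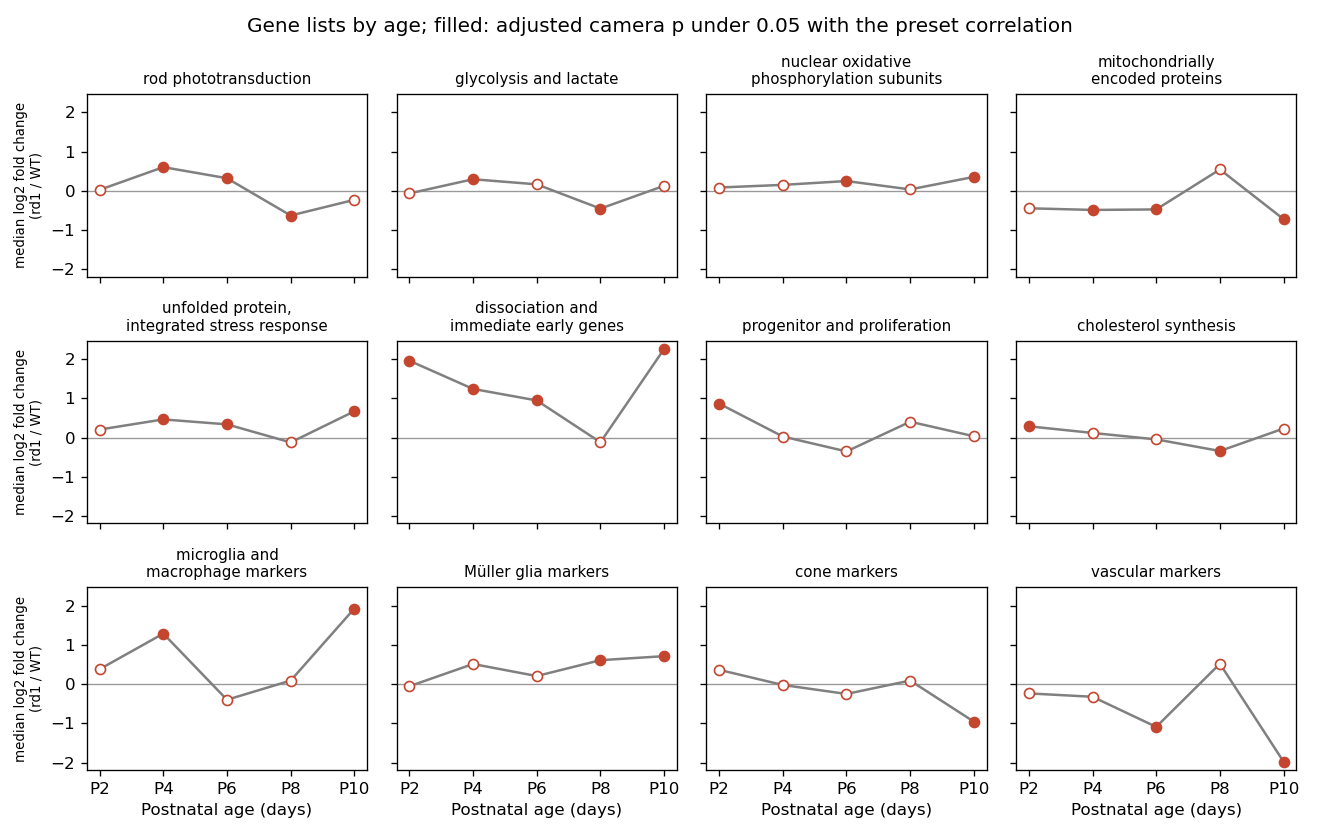
Median log2 fold change of rd1 over WT (y axis) by postnatal age (x axis) for 12 gene lists, 1 panel each; filled points have a camera adjusted p under 0.05 with the preset correlation, and none of the rd1 lists passed with an estimated correlation. The dissociation and immediate early list stands at 1.96, 1.24, 0.95, -0.12 and 2.26 from P2 to P10, and the phototransduction list changes sign between P6 (0.32) and P8 (-0.63).

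Averaged over the 5 ages with equal weight, the comparison asked how rd1 rods differed over the series as a whole. Lower genes were Col17a1 (-5.74 ± 0.20), Slc15a2 (-4.70), Eps8l1 (-4.32), Phf24 (-3.62), AA623943 (-3.47), Tmsb15b1 (-3.34) and Ahcy (-3.31). Duxbl1 was low or absent at each age. Sfrp4 rose by 3.52 ± 0.24, Sox30 by 3.49, Klhl33 by 3.42, Masp2 by 3.23, Erdr1 by 3.06, Capn11 by 2.97, Orm2 by 2.93 and Acot1 by 2.80. Bub1b fell by 1.73, while Slc7a11 rose 2.46-fold and Nefh by 0.91. All 41 genes taken by the naming rule and followed on the average kept their call without any 1 library.

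On the average, 15 of 18 dissociation and immediate early genes were higher and 3 not past the threshold (15 adjusted over the list alone; median 1.58, adjusted p = 3.19e-08, adjusted p = 0.984 with an estimated correlation), Jund at 1.77 and Nr4a1 at 1.44 among them. The stress response list had 12 of 23 higher and 11 not past it (13 adjusted over the list alone; median 0.29, adjusted p = 0.000453), with Trib3 at 1.24, Atf5 at 0.74, Ddit3 at 0.72 and Eif2ak3 at 0.49. Nuclear subunits of oxidative phosphorylation had 31 of 72 higher, 3 lower and 38 not past (33 and 4 adjusted over the list alone; median 0.18, adjusted p = 0.00322), with Cox6a1 at 1.13 and Cox8a at 0.87. Müller glia markers had 5 of 13 higher (9 adjusted over the list alone; median 0.45, adjusted p = 0.0137), Sox9 at 1.35 among them. The mitochondrially encoded list had 3 of 13 lower (3 adjusted over the list alone; median -0.34, adjusted p = 0.0499). Each of these had an adjusted p = 0.984 with an estimated correlation. At P8 the medians of 3 of the 5 had the other sign, -0.12 for the dissociation list, -0.125 for the stress response list and 0.55 for the mitochondrially encoded list, none past the threshold. Leaving out 1 library ended the pass of the mitochondrially encoded list for 11 different libraries and of none of the other 4 lists. The prohibitin genes moved apart, Phb at -0.52 and Phb2 at 0.36, and Rax (1.21), Chchd10 (1.16), Sdhc (0.47) and Bbc3 (1.44) were higher, while the inhibitory neuron genes Slc6a9 (-0.62) and Lhx1 (-1.17) were lower.

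In total, 4378 genes passed on the average, 2404 higher and 1974 lower, 929 of them pseudogenes or predicted genes. Of all genes, 5624 passed when P8 was left out of the average, an alternative added after the data were seen. In all, 37 of the 180 tests of 30 lists in 6 comparisons passed with camera at its preset correlation, and 22 of the 37 kept it without any 1 library. With camera 0 did with an estimated correlation, where 4 had an unadjusted p under 0.05, and 11 did by fry. Estimated correlations were 0.752 for phototransduction at P4, 0.503 for the dissociation list at P2 and 0.235 for cholesterol synthesis at P2. The preset of 0.01 is far lower, so p-values at the preset take list members as nearly independent. The 14 lists that passed in none of these 6 comparisons with camera at its preset correlation were those for outer segment and connecting cilium, photoreceptor transcription factors, rod ribbon synapse, retinal pigment epithelium, red blood cells, crystallins, the citric acid cycle, mitochondrial dynamics, fatty acid and ketone oxidation, cell death, photoreceptor damage, interferon response, calcium handling and cyclic nucleotides. Their smallest camera adjusted p was 0.055, for the outer segment list at P6. By fry 2 of the 14 did pass, fatty acid and ketone oxidation at P4, P6 and P8 and crystallins at P10 (adjusted p = 0.0495 each).

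Across ages, 143 genes passed in 1 direction at all 5 ages, 67 higher and 76 lower, Pde6b, Duxbl1, Col17a1, Slc15a2, Eps8l1 and Ahcy among the lower ones. Not all of these are separate signals. Rpl35a-ps2, Rpl35a-ps3, Rpl35a-ps4, Rpl35a-ps6 and Gm10243 had identical log2 fold changes at each age, as did Fam205a4 and Fam205a2, and each was counted as a gene. P2 and P4 shared 158 higher genes, where 4.26 were expected by chance, and 147 lower genes, where 3.45 were expected. Log2 fold changes across genes correlated at 0.601 to 0.665 between pairs of P2, P4, P6 and P10, and at 0.225 to 0.335 between P8 and each other age; genes are not independent replicates. Of the 731 genes past the threshold in 1 direction at 2 or more ages, 71 passed at P2, P4, P6 and P10 but not at P8, and 16 genes passed in opposite directions at some pair of ages. Many of the 143 lay in clusters, with 18 lower genes on chromosome 2 between 175166255 and 177478129 and 8 lower genes on chromosome 4 between 41966058 and 42944752.

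**Figure D4:**
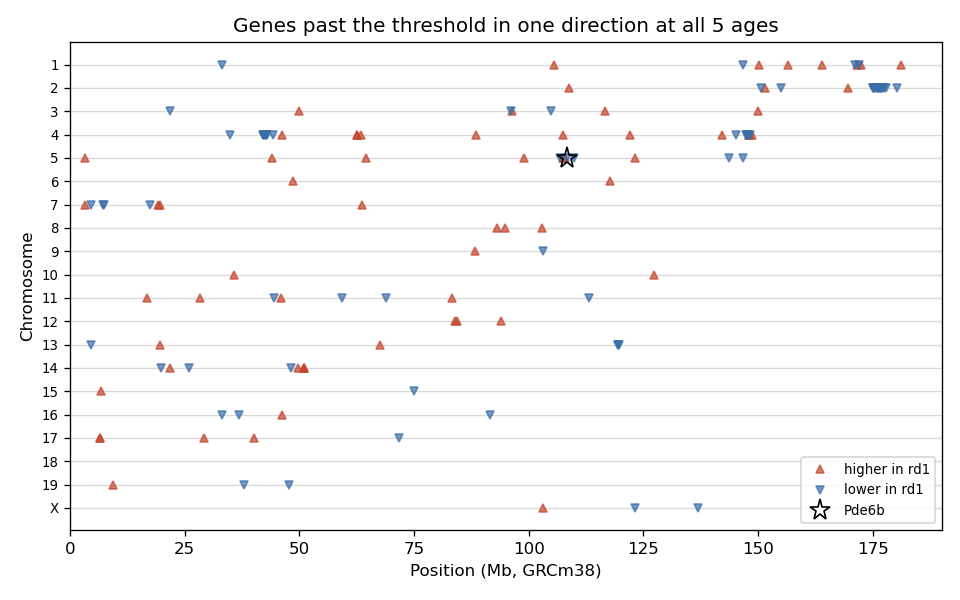
Positions in Mb on GRCm38 (x axis) by chromosome (y axis) of the genes past the threshold in 1 direction at all 5 ages, higher in rd1 as upward and lower as downward triangles, with Pde6b as a star. Of 141 such genes on placed chromosomes, 27 lie on chromosome 4, 25 on chromosome 2 and 12 on chromosome 5.

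Genes near Pde6b were compared with the rest of the genome. Within 20 Mb, 126 of 442 tested genes (28.5%) passed on the average, against 4225 of 18060 elsewhere (23.4%), an odds ratio of 1.31 (95% interval 1.05 to 1.62, Fisher's exact test, two-sided, p = 0.0145). Within 10 Mb the odds ratio was 1.56 (p = 0.0018, exact) and within 5 Mb it was 1.71 (p = 0.00704, exact). Hfm1, a meiotic helicase gene, and Fam69a were among the genes past the threshold at all 5 ages within 5 Mb. These counts include Pde6b, which the mutation itself lowers. Without it 125 of 441 genes (28.3%) passed within 20 Mb (p = 0.017, exact), and the odds ratio was 1.54 (p = 0.00232, exact) within 10 Mb and 1.67 (p = 0.00953, exact) within 5 Mb. For the genes of all 5 ages, again without Pde6b, it was 1.85 (p = 0.152, exact) within 20 Mb, 2.81 (p = 0.0381, exact) within 10 Mb and 4.58 (p = 0.0135, exact; 4 genes) within 5 Mb. For those of P8 it was 1.18 (p = 0.444, exact), 1.60 (p = 0.0881, exact) and 2.37 (p = 0.0142, exact). The averaged odds ratio within 20 Mb was not past the threshold in 4 alternatives. It was 1.23 (p = 0.0621, exact) without P6 WT replicate 4, 1.15 (p = 0.17, exact) without the 2 libraries that stand apart, 1.19 (p = 0.111, exact) by DESeq2 and 1.16 (p = 0.142, exact) by limma-voom.

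Some gene symbols share sequence with copies, so their values are uncertain. Rpl35a, a ribosomal protein gene, averaged 155 CPM in WT and 56.5 CPM in rd1, and its 4 pseudogene copies together averaged 0.258 CPM in WT and 54.5 CPM in rd1. The laminin receptor gene Rpsa averaged 382 CPM in WT and 177 CPM in rd1, while its 2 copies rose from 0.373 to 378 CPM. Pcna averaged 74 and 70.9 CPM, and its copy 0.013 CPM in WT and 7.75 CPM in rd1. Only copies named after their parent gene were compared. Other lower genes, Ahcy among them, were not checked for copies under other symbols, so reads assigned to such copies could lower their values.

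The rd1 effect differed among ages for 190 genes by the interaction test. Pttg1, the securin gene of dividing cells, had log2 fold changes of 1.46, 1.02, -0.27, -2.02 and -3.09 from P2 to P10 (adjusted p = 3.47e-06). Mmp2, a matrix protease gene, went from 3.00 at P2 to -0.09 at P10 (adjusted p = 3.98e-06), and Ptprn from 0.33 at P2 to 2.44 at P8 and 4.96 at P10 (adjusted p = 3.98e-06). Twsg1 (2.00 at P10, adjusted p = 1.22e-05), Ctnnal1 (2.35, 3.4e-05), Hspa1b (6.16, 6.64e-05) and Eif2ak3 (1.95, 6.64e-05) differed mainly at P10, and the pseudogene Rps2-ps10 stood at 6.23, 6.55, 6.98, -0.52 and 3.00 (adjusted p = 2.14e-06). The effect at P10 differed from that at P2 for 31 genes, 20 with the higher value at P10. The 190 genes depended on single libraries, from 41 without P8 WT replicate 1 to 818 without P2 WT replicate 2, and 19 of the 27 samples left out in turn moved it by over 1.5 times.

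Between P2 and P10 in WT, the comparison gave the change with age in the sorted libraries, though sex was not balanced between these ages. Markers of progenitor, bipolar and vessel cells changed too. Change within rods was therefore not told apart from change in other cells sorted with them. All 23 phototransduction genes rose, Slc24a1, the rod sodium-calcium exchanger, by 9.22 ± 0.83, Pde6a by 7.07 and Gucy2f by 6.31 (23 adjusted over the list alone; adjusted p = 3.82e-32, adjusted p = 0.0798 with an estimated correlation). Progenitor and proliferation genes fell in 29 of 30 cases, Mki67 by 5.97, Fgf15 by 5.88 and Top2a by 4.80 (30 adjusted over the list alone; adjusted p = 1.7e-24, adjusted p = 0.103 with an estimated correlation). Pde6b rose by 2.48. Outer segment genes had 19 of 26 higher and 1 lower, Impg1 at 4.44 and Abca4 at 3.23 (19 and 1 adjusted over the list alone; adjusted p = 4.24e-10, adjusted p = 0.294 with an estimated correlation). Ribbon synapse genes had 11 of 22 higher and 2 lower, Cabp4 at 5.80 (13 and 2 adjusted over the list alone; adjusted p = 1.72e-06, adjusted p = 0.17 with an estimated correlation). Calcium genes had 17 of 35 higher and 2 lower (18 and 2 adjusted over the list alone; adjusted p = 5.84e-05, adjusted p = 0.0798 with an estimated correlation). Esrrb, an orphan receptor gene of rods, rose by 7.50, while the early photoreceptor genes Prdm1 (-2.22) and Otx2 (-1.70) fell.

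Metabolic genes also changed with age in WT. Glycolysis and lactate genes had 15 of 29 higher and 3 lower, Slc16a1 at 3.78 and Hk1 at 3.63 (15 and 3 adjusted over the list alone; adjusted p = 0.000625, adjusted p = 0.317 with an estimated correlation). Nuclear subunits of oxidative phosphorylation had 24 of 72 higher and 1 lower (26 and 1 adjusted over the list alone; adjusted p = 8.71e-05, adjusted p = 0.714 with an estimated correlation). Cholesterol synthesis had 9 of 20 lower and 1 higher, Srebf2 at -2.11 and Insig1 at -1.76 (12 and 2 adjusted over the list alone; adjusted p = 0.0136, adjusted p = 0.499 with an estimated correlation). Cell death genes had 8 of 24 lower and 1 higher, Apaf1 at -1.54 (8 and 1 adjusted over the list alone; adjusted p = 0.0342, adjusted p = 0.348 with an estimated correlation). Cyclic nucleotide genes had 8 of 20 higher and 3 lower (8 and 3 adjusted over the list alone; adjusted p = 0.0199, adjusted p = 0.425 with an estimated correlation).

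Of the markers of other cells, 3 lists passed in WT. Bipolar markers had 12 of 15 higher and 1 lower, Grm6 at 9.10 and Scgn at 7.80 (13 and 1 adjusted over the list alone; adjusted p = 3.15e-09, adjusted p = 0.294 with an estimated correlation). Vessel markers had 9 of 12 higher (10 adjusted over the list alone; adjusted p = 0.0136, adjusted p = 0.714 with an estimated correlation) and microglia markers 4 of 16 higher (2 adjusted over the list alone; adjusted p = 0.0433, adjusted p = 0.734 with an estimated correlation). The lists of amacrine and horizontal cells (3 higher and 6 lower), ganglion cells (1 and 2), Müller glia (3 and 3) and cones (7 and 5) did not pass. Drd4, a dopamine receptor gene, rose by 8.90 and Gabrr1 by 8.43. Olig2, a progenitor transcription factor gene, fell by 7.20, Mfap4 by 6.65, St14 by 6.31 and Epha8 by 6.26. In total 6195 genes passed, 3063 higher and 3132 lower, and the genes named here kept their call without any 1 library.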

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

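The relabellings of genotype were planned before the result was seen, while the contrast of P8 with the other ages and both tests on P8 were chosen after the result was seen.

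In groups of 4 samples, 19 of 164 sets of values had 1 sample far from the other 3, where chance gives about 5% or 8.2. P6 WT replicate 1 held 27119 genes with a count, 11.5% of its counts in the top 10 genes, Fos at 269.5 CPM, Gm42418 at 318.2 CPM, Klhl33 at 4.11 CPM, Cox6a1 at 203 CPM, Jund at 188 CPM and Jun at 330 CPM. P10 WT replicate 5 held Pde6b at 4751 CPM, Fos at 591.1 CPM and Mt1 at 0.439 CPM, and P10 WT replicate 4 held Nrtn at 2.42 CPM and Ptprn at 40.7 CPM. In the remaining groups Capn11 stood at 4.29 CPM in P6 WT replicate 3, Nipal1 at 0.395 CPM in P6 WT replicate 2, Duxbl1 at 0.39 CPM in P8 rd1 replicate 2, Tmem92 at 3.09 CPM and Gnat1 at 241 CPM in P8 rd1 replicate 4, and Mvd at 10.3 CPM in P8 rd1 replicate 1.

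The rd1 effect differed among ages by the interaction test for 190 genes. Of 100 relabellings of genotype within age, the real one included, 1 gave as many, and the highest of the others gave 71. The relabellings also broke the genotype difference that the ages share, which adds to the spread within groups. They therefore cannot decide whether chance gave this count. The count was 451 and 818 without P2 WT replicates 1 and 2, 109 without P4 rd1 replicate 1, 114, 301 and 109 without P4 WT replicates 1, 2 and 3, 125 and 102 without P6 rd1 replicates 1 and 2, and 471 without P6 WT replicate 1. It was 108, 102, 83 and 69 without P8 rd1 replicates 1 to 4, 41 without P8 WT replicate 1, 95 and 56 without P10 rd1 replicates 1 and 2, and 105, 115 and 488 without P10 WT replicates 3, 4 and 5. The genes with the smallest adjusted p were Rps2-ps10 (2.14e-06), Pttg1 (3.47e-06), Mmp2 (3.98e-06), Ptprn (3.98e-06), Twsg1 (1.22e-05), Ctnnal1 (3.4e-05), Hspa1b (6.64e-05) and Eif2ak3 (6.64e-05). The rd1 effect at P10 differed from that at P2 for 31 genes, between 12 without P10 rd1 replicate 2 and 86 without P10 WT replicate 5; the count was 18 without P2 rd1 replicate 2, 19 without P2 WT replicate 1 or replicate 2, and 49 without P6 WT replicate 1.

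The rd1 effect at P8 differed from the mean of the other ages for 1788 genes, 568 with a higher and 1220 with a lower value at P8. The lists past the threshold for this difference, by camera adjusted p, were dissociation and immediate early genes (2.34e-07), glycolysis and lactate (2.34e-07), rod phototransduction (2.37e-07), the stress response (2.01e-05), cholesterol synthesis (0.000154), fatty acid and ketone oxidation (0.00594), nuclear oxidative phosphorylation subunits (0.0279) and outer segment genes (0.0279) with lower medians at P8. Those with higher medians at P8 were mitochondrially encoded proteins (2.62e-05), vessel markers (0.0107), amacrine and horizontal markers (0.0231) and bipolar markers (0.0279). None of these 12 passed with an estimated correlation, where the adjusted p of the glycolysis list was 0.379. The count was 2 without P8 WT replicate 1, 903 without P8 rd1 replicate 4, 1134 without P8 rd1 replicate 3, 1107 without P10 rd1 replicate 2 and 2867 without P2 WT replicate 2.

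The lower phototransduction and glycolysis lists in rd1 at P8 were weighed against 2 explanations. A candidate is that P8 WT replicate 1 was further in maturation than its partner, and without it the phototransduction median moved from -0.63 to -0.0947, within 0.153, the SE of the list mean, so that part of the pattern stays open. Without P8 WT replicate 2 the phototransduction median was -1.15 (adjusted p = 4.82e-13), and the glycolysis median stayed at -0.41 without replicate 1, with an SE of 0.196. A lag of rd1 rods along the WT maturation program would give a negative slope of the P8 effect on the WT change from P6 to P10. Across genes that slope was -0.0746 with P8 WT replicate 2 alone (correlation -0.0693) and -0.373 with replicate 1 alone (correlation -0.292). The slopes at P2 and P4, ages with other depth classes, were -0.123 and -0.0186. That at P2 was steeper than that at P8 with replicate 2 alone. A negative slope thus does not single out a lag at P8, which stays open. The difference between 2 WT libraries cannot tell biology from handling.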

How the results depend on the processing

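The average without P8, the single test of P8 against the other ages, the fits with all 28 libraries, without P6 WT replicate 1 and P10 WT replicate 5 together, and the near-Pde6b sets by age and without Pde6b itself were chosen after the result was seen; the other alternatives were planned. The averaged Pde6b log2 fold change kept its direction and call in each alternative run, from -1.87 to -1.73 with 1 library left out. No named gene, Pde6b value or odds ratio reversed its direction. The ganglion cell list at P10 had a negative median with the replicate block, not past the threshold, and at P6 the balance of higher and lower genes turned by DESeq2. Of the 287 pairs of a named gene and a comparison, 257 were past the threshold, and 168 of those kept the call in each alternative other than the replicate block and 145 in all of them.

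With a replicate block, although the numbers did not pair the samples, the counts were 162, 150, 117, 126 and 69 from P2 to P10, 1580 on the average, 1 for the interaction, 0 for P10 minus P2 by edgeR (1127 at an unadjusted p under 0.05, and 134 by DESeq2 without the block), 2976 for WT, 64 for P8 against the other ages and 26 for all 5 ages; the block takes residual degrees of freedom. With all 28 libraries kept apart the counts were 1284 at P6, 321 for the interaction and 56 for P10 minus P2. Without the 2 libraries that stand apart they were 934 at P2, 1069 at P4, 1376 at P6, 934 for the interaction, 96 for P10 minus P2 and 3261 for P8 against the others. With only the libraries of each age they were 303 at P2, 208 at P6, 1222 at P10 and 81 for all 5 ages. By the DESeq2 Wald test they were 826 at P2, 901 at P4, 804 at P6, 1033 at P8, 1177 for the interaction and 134 for P10 minus P2, and by limma-voom with library weights 2081 at P4, 1962 at P6, 1128 at P8 and 5264 at P10. With no filter on low counts they were 936 for the interaction and 85 for P10 minus P2, and 63 lists passed. With an adjusted p under 0.01, 88 genes passed at all 5 ages. The lists past the threshold were 0 with an estimated correlation (4 at an unadjusted p under 0.05) and 11 by fry. The main counts for these were 522, 549, 489, 688 and 2352 from P2 to P10, 4378 on the average, 190, 31, 6195, 1788, 143 for all 5 ages and 37 lists. At P6, 365 genes were higher and 439 lower by DESeq2, against 272 and 217. The cause of these moves was not tested.

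The odds ratio near Pde6b was 1.15 (p = 0.17, Fisher's exact test) without the 2 libraries that stand apart, 1.19 (p = 0.111, exact) by DESeq2, 1.16 (p = 0.142, exact) by limma-voom, 2.15 (p = 0.0527, exact) for the genes of all 5 ages and 1.24 (p = 0.37, exact) for those of P8; the last 2 rest on fewer genes. These include Pde6b itself, and without it the last 2 were 1.85 (p = 0.152, exact) and 1.18 (p = 0.444, exact), and 4.58 (p = 0.0135, exact) and 2.37 (p = 0.0142, exact) within 5 Mb. Left out 1 library at a time, the counts spanned 207 to 900 at P2, 195 to 873 at P4, 196 to 1023 at P6, 171 to 862 at P8, 463 to 2934 at P10, 41 to 818 for the interaction, 12 to 86 for P10 minus P2 and 2 to 2867 for P8 against the others, and the odds ratio 1.23 to 1.43. The counts on the average (3382 to 4997) and in WT (4364 to 6529), the lists past the threshold (34 to 46) and the genes of all 5 ages (101 to 165) stayed within 1.5 times. A group left with 1 sample is assumed to vary like the others. DESeq2 size factors moved no median log2 fold change of all genes beyond 0.049, and at single ages depth and sample number allowed recovery of 23% to 42% of simulated 2-fold changes.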

Other observations

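Among the tests in this part, those on chromosome segments, on copies, on Pde6b function, on the share outside 20 Mb of Pde6b and on the odds ratios without Pde6b itself were chosen after the result was seen; the averaged odds ratio near Pde6b, the relabellings and the tests on P6 and P10 were written before.

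Cone genes did not move as 1 group. Gngt2, the cone transducin gamma gene, was higher in rd1 at P8 (1.51) and P10 (2.08), while it fell by 3.53 from P2 to P10 in WT. Pde6c, Kcne2 and Opn1mw were lower in rd1 at P10. Thrb, the thyroid hormone receptor gene of cone patterning, rose by 2.14 in WT from P2 to P10 and was higher in rd1 at P2 (1.23) and P4 (1.04). The vessel gene Pecam1 rose by 2.64 in WT and was lower in rd1 at P10 (-1.84), and the bipolar gene Scgn rose by 7.80 and was lower in rd1 at P10 (-1.99). The WT change and the rd1 effect at P10 share the P10 WT libraries, and the effect at P2 shares the P2 WT libraries. Values in those libraries alone could give such patterns, so the 2 contrasts are not separate observations. The effects of Gngt2 at P8 and Thrb at P4 rest on other WT libraries.

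The count of 4378 genes on the average was matched by 1 of 100 relabellings of genotype within age, the real one, and the highest of the others gave 2428. Random labels are thus an unlikely source of this count, though 100 relabellings cannot exclude them. That highest relabelling kept the real genotype of 19 of the 27 samples.

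The 143 genes past the threshold in 1 direction at all 5 ages were weighed against 3 explanations. Segments of another strain in the rd1 line are a candidate, since 45.4% of the 141 placed genes had another within 1 Mb, above the highest of 1000 random draws (32.6%). The random genes were not matched for families of neighbouring copies. Of the 143, 18 lay in 1 cluster on chromosome 2 and 8 in 1 on chromosome 4, so this excess cannot separate segments from copies. The odds ratio near Pde6b on the average was 1.31, with p from 0.0621 to 0.17 (exact) in 4 alternatives. For the 143 without Pde6b itself it was 1.85 (p = 0.152, exact) within 20 Mb and 4.58 (p = 0.0135, exact) within 5 Mb. Of the genes past the threshold on the average, 97.1% of those with a position lay outside 20 Mb of Pde6b. The few genes tested within it fixed that share at 89.8% or more. Outside it 4225 genes passed (23.4% of those tested), against 126 within it (28.5%). With 442 genes tested within 20 Mb, a segment that changed only its own genes could not supply most of the 4378, whatever the values. The share outside therefore does not test a segment as an explanation. Effects of such a segment on genes elsewhere were not tested. Reads moving between near-identical copies could add to the 143 genes. Of these, 56.6% were predicted genes, pseudogenes or genes with a named pseudogene, against 21.7% of all tested genes, though a predicted gene need not be a copy. Copies with identical values, such as those of Rpl35a, were each counted. Loss of Pde6b function cannot be told apart from the rest of the rd1 genome, because 0 groups separate the mutation from that genome.

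The 365 genes past the threshold in the same direction at P6 and P10 were weighed against a library batch that the rd1 libraries of P2, P4, P6 and P10 share and P8 lacks. The median P8 effect was 0.674 (bootstrap SE 0.026) of the mean P6 and P10 effect, above the 0.5 set beforehand. This argues against that batch as the only source of the 365 genes and goes with a genotype difference that persists from P6 to P10. Genes past the threshold at P2 and P6 kept 0.956 of their effect at P4, so P8 still stood apart. The share at P8 was 1.01 among the 143 genes past the threshold at all 5 ages, a set picked in part for passing at P8. Among the other 222 genes it was 0.267, under 0.5, and 27.5% of them had the opposite sign at P8. That set was also partly picked by its P8 value, so a batch may account for part of these genes. Depth class stays confounded with genotype at the other ages.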
